A study of Rattus norvegicus with 12 samples.

How the data were processed

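RNA from the left ventricle was extracted with a kit for fibrous tissue and 6 µg of total RNA per array was turned into biotin-labelled cRNA, per the labels' protocols. The series was measured on Affymetrix Rat Genome GeneChip arrays, on which a probe set is a group of short probes for 1 transcript. The authors deposited 1 table of log2 values with 2 decimals for 31099 rows and 12 arrays. The submitters' processing notes name MAS5 and RMA without saying which made these values, so their exact scale and background correction stay open. The values have the range of a log2 scale and were used as deposited, since the array medians lay within 0.2 of each other, the tolerance fixed beforehand.

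Each array was assigned to EX, PA or SED from its title and description. The 57 control rows were left out of all tests. Of the rows, 20826 had 1 gene symbol, 436 had several and 9780 had none listed, and only probe sets with 1 symbol were named. Looked up through their gene identifiers, 20758 symbols were unchanged and 68 identifiers were not found and kept their symbol. Probe sets in the upper 60% by mean log2 over all 12 arrays were tested, 18626 of 31042, with the filter at 4.94. A gene was represented by its tested probe set with the highest mean, which gave 10244 genes, of which 2626 had more than 1 tested probe set.

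Differences between groups were tested with limma 3.58.1 in R 4.3.3, as a linear model with 3 group means over all 12 arrays (9 residual degrees of freedom) and moderated two-sided tests, adjusted by Benjamini-Hochberg over the tested probe sets with a threshold of 0.05. Standard errors and 95% intervals come from that model. Differences are on the log2 scale. The comparisons are EX against SED, PA against SED, EX against PA, and a moderated F test over the groups. Gene lists were tested with camera of limma (preset correlation of 0.01, lists of 5 or more tested genes, adjusted over the lists of a comparison), and beside it with an estimated correlation and with fry. There were 29 lists with 794 entries, of which 709 matched a symbol on the array and 617 were tested, with 12 genes on more than 1 list. With all 12 arrays, no adjusted p with an estimated correlation was under 0.929 in any comparison.

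The design, the lists, the alternatives and the rule for named genes were written before the data were examined. The rule names the 10 largest rises and falls past the threshold without overlap between the groups, or, if fewer than 10 genes qualify, the 10 genes with the smallest p, as was the case here. It adds up to 4 members of a list with the smallest p, and Nppa, Nppb, Myh6, Myh7, Atp2a2, Ppargc1a, Pdk4, Ucp3, Hspa1a and Dbp whatever their values. The control probe sets for the 5' and 3' ends of Gapdh and beta-actin served as a check of RNA integrity. Arrays carry no read depth, and precision rests on their number.

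The alternatives were quantile normalization, centring of array medians, no filter and a stricter filter, an offset of 32 on the linear scale, a variance model with trend and robust estimation, array weights, a fit of the compared groups only, the replicate number as a block, a threshold of 0.1, a minimum of 1.2-fold, averaged probe sets, and leaving out each array in turn. Cyclic loess, the comparison of EX and PA together with SED, its alternatives, and the lists without SED 1 and SED 3 together and the lists with an estimated correlation without SED 1, without EX 4 or without SED 1 and SED 3 were chosen after seeing the data. A smaller offset was planned for linear values only and so was not run.

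The steps were tested on simulated data with 18626 probe sets, some of them changed by a known amount. With real residuals as noise, the EX against SED step recovered 26.5% of 68 probe sets changed 1.5-fold, 79.5% of 73 changed 2-fold and 93.2% of 59 changed 3-fold, with 0 false calls. At the same folds the PA against SED step recovered 29.9% of 67, 75.8% of 66 and 92.5% of 67, and the EX against PA step 26.8% of 56, 77.9% of 68 and 97.4% of 76, with 0 false calls each. These residuals were centred within each group, so unchanged probe sets differed by exactly 0 and the 0 false calls were fixed in advance. The estimated change also equalled the true one, so the recovery leaves out error in the group means. With independent noise, false calls were 9.88%, 3.52% and 3.03% of the calls of those steps. In a simulation of 20 lists over 10244 genes, with noise independent between genes, camera called the 1 list that was moved and 0 of the others. Correlation between the members of a list was left out, so the simulation does not show how often camera's preset calls correlated lists falsely. The leukocyte list, for example, had an estimated correlation of 0.411. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.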

Results

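Gene expression in the left ventricle of 16-month-old female Sprague-Dawley rats was measured on Affymetrix Rat Genome GeneChip arrays. The EX group had lifelong access to voluntary exercise, the PA group had 1 h of activity in a large box on 2 occasions a week, and the SED group had a standard cage only. Each group had 4 arrays. The design text gives 12 animals per group with 4 pooled on each array, which would fill 3 arrays per group, while 4 are listed for each. Which animals stand behind which array was therefore not settled, and the p-values below measure the spread between these pooled arrays. The number of arrays limits the precision of every value.

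The deposited log2 values were alike in level over the 12 arrays, with medians from 5.64 to 5.72. Their spread was not: the interquartile range was 3.75 ± 0.128 (SD, n = 4) in SED and 3.98 ± 0.0525 (SD, n = 8) over the EX and PA arrays, and the highest SED array (3.86) lay under the lowest of the other 8 (3.89). SED 1 stood apart from the rest, with a mean correlation of 0.964 with the other 11 arrays against 0.987 to 0.989 for those arrays. It also had the largest 3' minus 5' difference of the Gapdh control probe sets, 1.56 log2 units against 0.96 to 1.35. For the beta-actin controls the difference was 1.70 in SED 1 and 1.37 to 1.67 elsewhere. The 5S ribosomal RNA probe set read 7.72 in SED 1 and at most 6.74 on the other arrays.

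The EX against SED comparison asks how the ventricle differs between lifelong voluntary exercise and a standard cage. No probe set passed an adjusted p of 0.05, so the genes with the smallest p-values are given by their values. Ripor1, an inhibitor of the small GTPase RhoA, stood at 5.67 ± 0.11 in EX and 6.37 ± 0.13 in SED (log2, SD, n = 4 each), a difference of -0.70 ± 0.09 (SE) with an adjusted limma p of 0.0808. Tc2n, a C2-domain protein, stood at 6.89 ± 0.16 in EX and 5.36 ± 0.53 in SED, a difference of 1.53 ± 0.23 (SE) with an adjusted p of 0.0939 by limma. Ing3, a subunit of a histone acetyltransferase complex, differed by 0.68 ± 0.11 (SE) and Ccm2l, an endothelial protein related to Ccm2, by 0.60 ± 0.10, each with an adjusted limma p of 0.115.

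The other genes with the smallest p-values in EX against SED all had an adjusted limma p of 0.115 as well. The EX mean was above the SED mean by 0.84 for Steap2, a metalloreductase, by 0.67 for Akap9, a protein kinase A anchoring protein, and by 1.10 for Tmco1, a calcium channel of the endoplasmic reticulum. It was above it by 0.60 for Polr1h, a subunit of RNA polymerase I, and by 0.72 for Sft2d3. For Misfal the difference was -0.64. In all 10 of these genes the 4 EX arrays and the 4 SED arrays did not overlap. Akap9 had a further tested probe set, which differed by 0.05 against 0.67 for the representative one.

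In total, limma placed 0 of 18626 probe sets past the threshold in EX against SED, with 2906 at an unadjusted p under 0.05 (1732 higher and 1174 lower in EX) where 931 are expected by chance. The median difference over all tested probe sets was 0.055, and 5.2e-05 after quantile normalization. Camera, which tests gene lists, found 1 list past its threshold. Of 10244 genes, 692 had no overlap between the 2 groups' arrays, 6.76% where chance gives 2.86%. With SED 1 left out 2 probe sets passed, with EX 2 left out 1 passed, with array weights 8 passed, and with the probe sets of a gene averaged 2 passed.

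**Figure D1:**
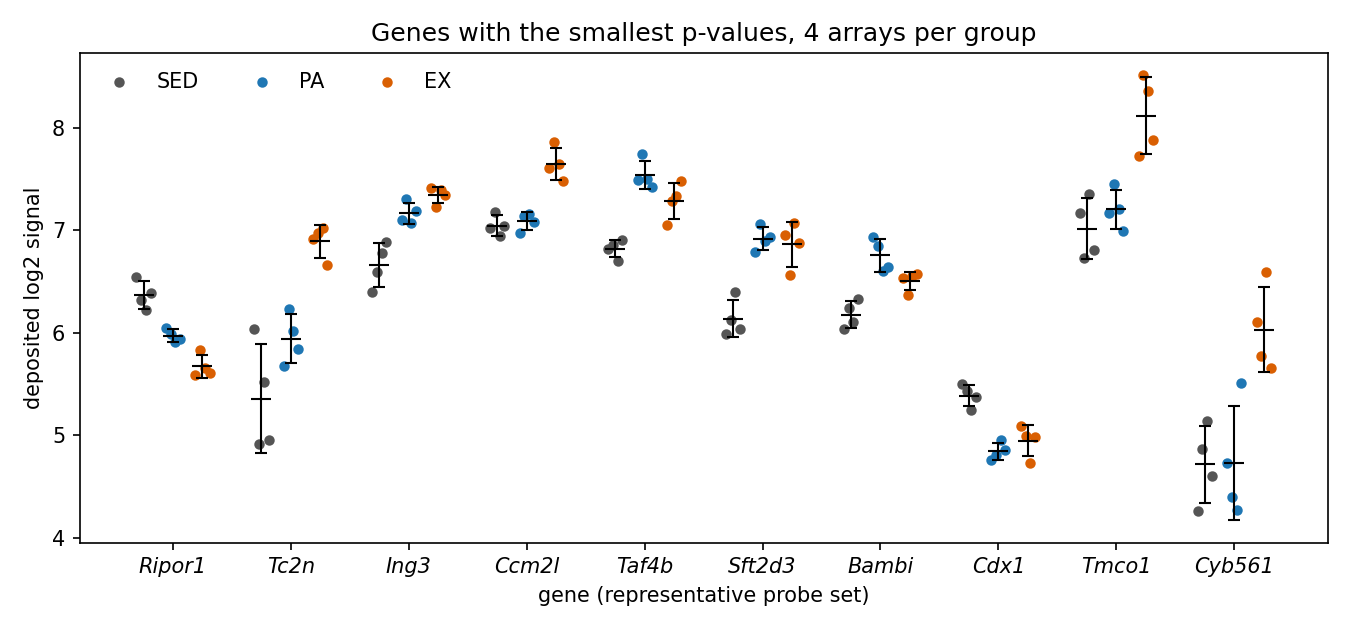
Deposited log2 signal (vertical axis) of 10 genes chosen among those with the smallest p-values (horizontal axis), with 1 point per array, 4 per group, and bars for the mean and SD. In Ripor1 the group means are 6.37 in SED, 5.97 in PA and 5.67 in EX, and in Tc2n they are 5.36, 5.94 and 6.89.

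Leukocyte genes were lower in EX than in SED as a list: 23 of 26 measured members had a lower mean in EX and 3 a higher one, with a median difference of -0.27 (camera adjusted p = 0.000114). With an estimated correlation between the genes the adjusted p was 0.975, and with fry it was 0.751. Laptm5, a lysosomal membrane protein of blood cells, differed by -0.38 ± 0.15 (SE), the complement subunit C1qc by -0.50 ± 0.19, the endotoxin receptor Cd14 by -0.49 ± 0.21 and the class II antigen gene RT1-Ba by -0.49 ± 0.21, and 0 of the 26 members passed the test over all genes or adjusted over the list alone. In SED 3 the mean of the list lay 0.74 above its mean over all 12 arrays, and 24 of the 26 members had their highest value there. The blood-cell list was also highest in SED 3, at 0.82 above its mean over all arrays against 0.27 in SED 4, the next highest. Of its members, the neutrophil genes S100a8 and S100a9 stood out most in SED 3, by 2.43 and 1.81 above their means. Without SED 3 the median difference was -0.10 and the adjusted camera p 0.389.

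Inflammation and cytokine genes had a median difference of -0.15 in EX against SED, with 15 of 24 members lower and 9 higher (camera adjusted p = 0.147). Here too SED 3 was the highest array, with a list mean 0.39 above the mean over all arrays. Irf1, an interferon-induced transcription factor, differed by -0.56 ± 0.15 (SE), the complement component C3 by -0.92 ± 0.25 and the chemokine Ccl5 by -0.57 ± 0.17. These 3 passed adjusted over the list alone (0.0389, 0.0389 and 0.0464 by limma), and 0 passed over all genes. Without SED 1, the list passed with an adjusted camera p of 0.00646, while its adjusted camera p with an estimated correlation was 0.925.

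Of the energy metabolism lists, none passed in EX against SED. Fatty acid uptake and oxidation had 19 of 30 members higher and 11 lower, with a median difference of 0.04 (camera adjusted p = 0.928), and Plin5, a lipid droplet protein, differed by -0.25 ± 0.10 (SE). Glucose uptake, glycolysis and glycogen had 11 of 26 members higher and 15 lower (median -0.03, camera adjusted p = 0.907). Without SED 1 this list had 6 higher and 20 lower, with a median of -0.03 (camera adjusted p = 0.418). Citric acid cycle genes were split 9 higher and 7 lower of 17 (camera adjusted p = 0.907). The nuclear-encoded genes of oxidative phosphorylation had 32 of 56 members higher and 22 lower (median 0.02, camera adjusted p = 0.928), and without SED 1 they had 21 higher and 35 lower (median -0.03). Regulators of mitochondrial biogenesis had 16 of 21 members higher and 5 lower (median 0.15, camera adjusted p = 0.147), among them Gabpa, a transcription factor of respiratory chain genes, at 0.34 ± 0.13 (SE) and the AMP-activated kinase subunit Prkaa1 at 0.21 ± 0.08. Without SED 1, the lowest array for these regulators, their median was 0.07 (camera adjusted p = 0.418).

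Contractile and electrical genes gave few differences between EX and SED. The hypertrophy and fetal-program markers had 9 of 16 members higher and 7 lower (median 0.02, camera adjusted p = 0.907), and the adult sarcomere and Z-disc genes had 7 of 20 higher and 13 lower (median -0.04, camera adjusted p = 0.834). Calcium handling and ion channel genes had 13 of 28 higher and 15 lower (median -0.01, camera adjusted p = 0.907). Within that list Kcnd2, a potassium channel of the transient outward current, differed by 0.96 ± 0.22 (SE) and Kcnj3, a G-protein-gated potassium channel, by 0.47 ± 0.13, at 0.0229 and 0.0456 by limma adjusted over the list alone. Over all genes their adjusted limma p was 0.134 and 0.144. Kcnj3 is also on the atrial tissue list, which had 6 of 10 members higher and 4 lower (median 0.17, camera adjusted p = 0.834), and there its value adjusted over the list alone was 0.0326. The EX arrays were split on the atrial list, with EX 1 and EX 3 at 0.31 and 0.54 and EX 2 and EX 4 at -0.31 and -0.39 relative to the mean over all arrays. Nppa, itself a member of that list, was split the same way in EX, at 10.74 and 10.92 against 10.22 and 10.05. Outside EX it did not always follow: SED 2 had the highest Nppa (11.06) with a list value of 0.05.

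For the genes fixed for report whatever their values, the representative probe sets had intervals that included 0 in EX against SED. The natriuretic peptide genes Nppa and Nppb differed by 0.30 (95% interval -0.40 to 1.00) and 0.14 (-0.23 to 0.50). The myosin heavy chains Myh6 and Myh7 differed by -0.03 (-0.18 to 0.12) and -0.27 (-0.57 to 0.03), and the calcium pump Atp2a2 by 0.0025 (-0.15 to 0.15). Ppargc1a, a coactivator of mitochondrial genes, differed by 0.12 (-0.15 to 0.38), the pyruvate dehydrogenase kinase Pdk4 by 0.20 (-0.38 to 0.77) and the mitochondrial carrier Ucp3 by -0.29 (-0.90 to 0.31). For the heat shock gene Hspa1a the difference was 0.25 (-0.11 to 0.61), and for the clock-controlled gene Dbp it was -0.04 (-0.40 to 0.33). The probe sets of Ppargc1a disagreed: the one with the highest mean gave 0.12 and the dimmest 0.73. For Pdk4 a dimmer probe set gave 0.60 against 0.20 for the representative one.

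Signalling, matrix and stress lists did not pass in EX against SED. Adrenergic, renin-angiotensin and natriuretic genes had 11 of 21 members higher (camera adjusted p = 0.907). Insulin, IGF and growth genes had 13 of 23 higher (camera adjusted p = 0.907). In that list Eif4ebp1, a repressor of translation, differed by -0.36 ± 0.09 (SE) at 0.0317 by limma adjusted over the list alone. Extracellular matrix and fibrosis genes had 27 of 36 higher (median 0.11, camera adjusted p = 0.834). Antioxidant genes had 18 of 31 higher (camera adjusted p = 0.907), and the glutathione synthesis genes Gss and Gclm differed by 0.70 ± 0.21 and 0.58 ± 0.19 (SE). The median of the matrix list was 0.06 without SED 1, and then the antioxidant list had 12 members higher and 19 lower, with its median going from 0.04 to -0.01. Angiogenesis and endothelial genes had 13 of 26 higher (camera adjusted p = 0.907), with the growth factor Vegfc at 0.62 ± 0.15 and the receptor Nrp2 at 0.53 ± 0.15 (SE), at 0.0411 and 0.0442 by limma adjusted over the list alone. Over all genes 0 members of the growth and the angiogenesis lists passed.

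Members with a higher EX mean numbered 13 of 26 among heat shock genes, 12 of 26 among proteolysis and autophagy genes, 11 of 17 among circadian clock genes, 9 of 17 among glucocorticoid-responsive genes, 10 of 17 among cell cycle and senescence genes and 20 of 30 among cytosolic ribosomal proteins. The camera adjusted p was 0.907 for each of these lists. Without SED 1 the ribosomal proteins had 13 members higher and 17 lower. Immediate early genes had 9 of 22 members higher and 12 lower (camera adjusted p = 0.834). Among markers of other cell types, blood cells (4 of 8 higher), adipocytes (7 of 13), skeletal muscle (2 of 6), smooth muscle and pericytes (4 of 11) and epicardium and mesothelium (4 of 7) each had a camera adjusted p of 0.907. For the blood-cell list 2 members were higher and 6 lower without SED 1, with the median going from 0.015 to -0.19. Nerve and Schwann cell genes had 4 of 6 members lower (median -0.18, camera adjusted p = 0.402), with the noradrenaline-synthesis enzyme Dbh at -0.42 ± 0.13 (SE) and 0.0354 by limma adjusted over the list alone. C3 is also on the epicardium list and stood at 0.0227 there. Over the 29 lists, 11 entries passed adjusted over the list alone in EX against SED, and 0 passed over all genes. The adjustment over a list alone does not allow for the number of lists. Camera sets a list against all other genes, and in 11 of the 29 lists its direction and the sign of the median differed.

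**Figure D2:**
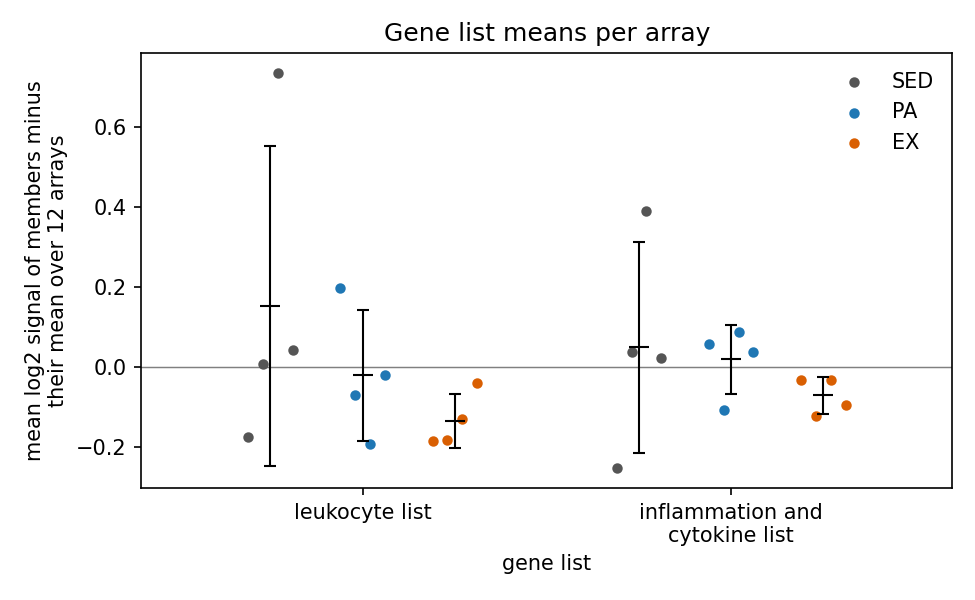
Mean log2 signal of the members of the leukocyte list and of the inflammation and cytokine list on each array, minus the members' mean over the 12 arrays (vertical axis), for the 2 lists (horizontal axis), with bars for the mean and SD of the 4 arrays of a group. SED 3 is the highest point in both lists, at 0.74 and 0.39.

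The PA against SED comparison asks how short sessions of activity in a large box differ from a standard cage. Again no probe set passed, and the 10 genes with the smallest p-values all had an adjusted limma p of 0.164. Taf4b, a subunit of the transcription factor TFIID, stood at 7.54 ± 0.14 in PA and 6.82 ± 0.09 in SED (log2, SD, n = 4 each), a difference of 0.72 ± 0.11 (SE). Sft2d3, also among the genes named for EX, stood at 6.92 ± 0.11 in PA and 6.14 ± 0.18 in SED, a difference of 0.78 ± 0.13 (SE). Bambi, a decoy receptor of the TGF-beta family, differed by 0.58 ± 0.10 (SE) and Mterf1, a mitochondrial transcription termination factor, by 0.46 ± 0.09.

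PA means lay under SED means for the other 6 of these genes. The differences were -0.54 for the homeobox gene Cdx1, -0.59 for the B-cell kinase Blk, -0.63 for Ribc2, -0.52 for Grpca, -0.56 for Fam221b and -0.55 for Hook2, an adaptor of the motor protein dynein. Cdx1, Blk, Fam221b and Hook2 had PA means of 4.78 to 4.90, near the filter on dim probe sets at 4.94. In all 10 genes the arrays of the groups did not overlap. In Grpca the PA 4 array read 6.95 against 7.07 to 7.08 for the other PA arrays.

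Over all probe sets, limma called 0 of 18626 in PA against SED, with 2840 at an unadjusted p under 0.05 (1728 higher and 1112 lower in PA). Camera called 1 list. Genes without overlap between the groups numbered 706 of 10244, or 6.89% where chance gives 2.86%. With array weights 1 probe set passed.

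Leukocyte genes again passed as a list, with 19 of 26 members lower in PA and 7 higher and a median difference of -0.10 (camera adjusted p = 0.0191). The adjusted p was 0.931 with an estimated correlation and 0.661 with fry. Cd14 differed by -0.69 ± 0.21 (SE), RT1-Ba by -0.53 ± 0.21 and the class II antigen gene RT1-Da by -0.60 ± 0.25, and 0 members passed over all genes or adjusted over the list alone. Without SED 3 the adjusted camera p was 0.831 and the median difference 0.02, opposite in sign to camera's direction. Without SED 1 the median difference was -0.26, with 23 of 26 members lower (camera adjusted p = 2.16e-05, or 0.952 with an estimated correlation). The call was also lost without PA 2 (camera adjusted p = 0.057), without PA 3 (camera adjusted p = 0.225) and with no filter on dim probe sets (camera adjusted p = 0.0713).

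Most energy metabolism genes had a higher mean in PA than in SED, in part through SED 1, and none of these lists passed. Over all tested probe sets the median difference was 0.0625 in PA against SED, and 0.0041 after quantile normalization. Part of the differences below was thus shared by probe sets in general. Of the members measured, 22 of 30 were higher for fatty acid uptake and oxidation (median 0.10, camera adjusted p = 0.459), 18 of 26 for glucose uptake, glycolysis and glycogen (median 0.06, camera adjusted p = 0.866) and 14 of 17 for the citric acid cycle (median 0.09, camera adjusted p = 0.367). For oxidative phosphorylation 43 of 56 were higher (median 0.08, camera adjusted p = 0.459). Regulators of mitochondrial biogenesis had 18 of 21 members higher (median 0.16, camera adjusted p = 0.149), with the mitochondrial transcription factor Tfam at 0.25 ± 0.09 (SE) and Gabpa at 0.30 ± 0.13. SED 1 was the lowest array for the mitochondrial regulators (-0.26), oxidative phosphorylation (-0.18), the citric acid cycle (-0.15) and the glucose list (-0.14), each relative to the mean over all arrays. Without SED 1 the median differences were 0.11, -0.0025, 0.04 and 0.02, with 27 of 56 oxidative phosphorylation genes higher in PA, and the mean of the glucose list changed sign from 0.02 to -0.03. The fatty acid list was at 0.09. Acsl1, which activates fatty acids, differed by 0.20 ± 0.09 (SE) and the complex I subunit Ndufb10 by 0.29 ± 0.12.

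The calcium handling and ion channel list had 19 of 28 members higher in PA (median 0.02, camera adjusted p = 0.866). Kcnj3 differed by 0.48 ± 0.13 (SE), its partner Kcnj5 by 0.46 ± 0.16 and Kcnd2 by 0.59 ± 0.22, and none passed adjusted over that list alone. Kcnj3 did so within the atrial list, at 0.0293 by limma, where 8 of 10 members were higher (median 0.05, camera adjusted p = 0.516). Over all genes 0 members of either list passed. Nppa differed by 0.21 (95% interval -0.49 to 0.91), Nppb by 0.13 (-0.24 to 0.50), Myh6 by -0.04 (-0.19 to 0.11), Myh7 by -0.12 (-0.42 to 0.17) and Atp2a2 by 0.01 (-0.14 to 0.16). Ppargc1a differed by 0.21 (-0.05 to 0.48), Pdk4 by 0.17 (-0.40 to 0.75), Ucp3 by -0.44 (-1.04 to 0.16), Hspa1a by 0.11 (-0.25 to 0.48) and Dbp by 0.11 (-0.25 to 0.47). These are the representative probe sets, and dimmer ones differed by 0.76 for Ppargc1a and 0.46 for Pdk4 in PA against SED.

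No other list passed in PA against SED. Immediate early genes (13 of 22 lower) and adipocyte genes (7 of 13 lower) each had a camera adjusted p of 0.367. Inflammation and cytokine genes had 14 of 24 members lower (median -0.03, camera adjusted p = 0.456), with SED 3 the highest array here too. The median was -0.09 without SED 1, with 19 of 24 lower, and the list passed with an adjusted p of 0.0241 by camera, while with an estimated correlation its adjusted p was 0.952. In 7 of the 29 lists the direction of camera and the sign of the median differed.

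EX against PA compares the 2 kinds of activity. No probe set passed, and the genes with the smallest p-values had adjusted limma p-values from 0.57 to 0.929. Ccm2l stood at 7.65 ± 0.16 in EX and 7.09 ± 0.09 in PA (log2, SD, n = 4 each), a difference of 0.56 ± 0.10 (SE). Tmco1 differed by 0.91 ± 0.20 (SE), Cyb561, a transmembrane electron carrier, by 1.30 ± 0.29, Tc2n by 0.95 ± 0.23 and Steap2 by 0.59 ± 0.14. The PA mean of Cyb561 was 4.73 ± 0.56 (SD), under the filter on dim probe sets at 4.94. Its PA 4 array read 5.51, close to the lowest EX array at 5.66. The ubiquitin ligase Znrf3, an inhibitor of Wnt signalling, differed by -0.59 ± 0.13 (SE), Apba3 by -0.38 ± 0.09 and the mast cell tryptase Tpsb2 by -0.50 ± 0.12.

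Also among these 10 genes were Itfg2 at 0.39 ± 0.09 (SE) and the replication factor Mcm10 at 0.49 ± 0.12. Their EX and PA arrays did not overlap, nor did those of the other 8 genes except Steap2. Limma called 0 of 18626 probe sets, with 534 at an unadjusted p under 0.05 (267 higher and 267 lower in EX). The 931 expected by chance assumes evenly spread p-values. Other splits of the EX and PA arrays gave 293 to 1136. The 534 lies within that range and does not show EX and PA to be more alike than chance gives. Groups without overlap were found for 280 of 10244 genes, 2.73% where chance gives 2.86%. With array weights 1 probe set passed.

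Genes of energy metabolism mostly had a lower mean in EX than in PA, by small amounts. Of the members measured, 24 of 30 were lower for fatty acid uptake and oxidation (median -0.05), 22 of 26 for glucose uptake, glycolysis and glycogen (median -0.07), 15 of 17 for the citric acid cycle (median -0.05) and 46 of 56 for oxidative phosphorylation (median -0.04). Their camera adjusted p-values were 0.202, 0.351, 0.202 and 0.202. Regulators of mitochondrial biogenesis had 8 of 21 members higher and 13 lower (median -0.0125, camera adjusted p = 0.995). The median difference over all tested probe sets was -0.01. Without EX 4 the fatty acid and the oxidative phosphorylation lists passed, each at an adjusted camera p of 0.0392, while with an estimated correlation the adjusted camera p of both was 0.82. Ccl5 was the 1 gene that passed adjusted over its list alone, at 0.0408 by limma in the inflammation list, with a difference of -0.69 ± 0.17 (SE), while its adjusted limma p over all genes was 1.00.

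The fixed genes differed little between EX and PA. Nppa differed by 0.09 (95% interval -0.61 to 0.79), Nppb by 0.0025 (-0.37 to 0.37), Myh6 by 0.01 (-0.14 to 0.16), Myh7 by -0.15 (-0.45 to 0.15) and Atp2a2 by -0.0075 (-0.16 to 0.14). Ppargc1a differed by -0.10 (-0.36 to 0.16), Pdk4 by 0.02 (-0.55 to 0.60), Ucp3 by 0.14 (-0.46 to 0.75), Hspa1a by 0.14 (-0.23 to 0.50) and Dbp by -0.15 (-0.51 to 0.22). Leukocyte genes had 19 of 26 members lower in EX (median -0.10, camera adjusted p = 0.351). Of the 29 lists, 0 passed with camera, 0 with fry and 0 with an estimated correlation. In 8 lists the direction of camera and the sign of the median differed.

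Over the 3 groups together, limma's F test called 0 of 18626 probe sets, with a smallest adjusted p of 0.173 and 2489 probe sets at an unadjusted p under 0.05. It called 2 without SED 1, 1 without EX 2 and 6 with array weights.

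The differences of EX and of PA from SED went together across probe sets, with a Pearson correlation of 0.787 and a covariance of 0.0592 over 18626 probe sets, which are not independent replicates. Both comparisons use the same 4 SED arrays. A simulation without change drew EX, PA and a shared SED group at random from the spread of each probe set, independently between probe sets. It gave a mean correlation of 0.713 and a covariance of 0.0375. The deposited SED arrays are not in it, nor are differences that many probe sets share on 1 array, so it is an incomplete baseline. When EX was set against 2 SED arrays and PA against the other 2, the correlation averaged 0.228 and the covariance 0.0228 over 6 splits. Without SED 1 the correlation was 0.697 and the covariance 0.0368. The remaining SED arrays are still shared there, and no simulation was run without SED 1, so these values have no baseline to be set against.

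**Figure D3:**
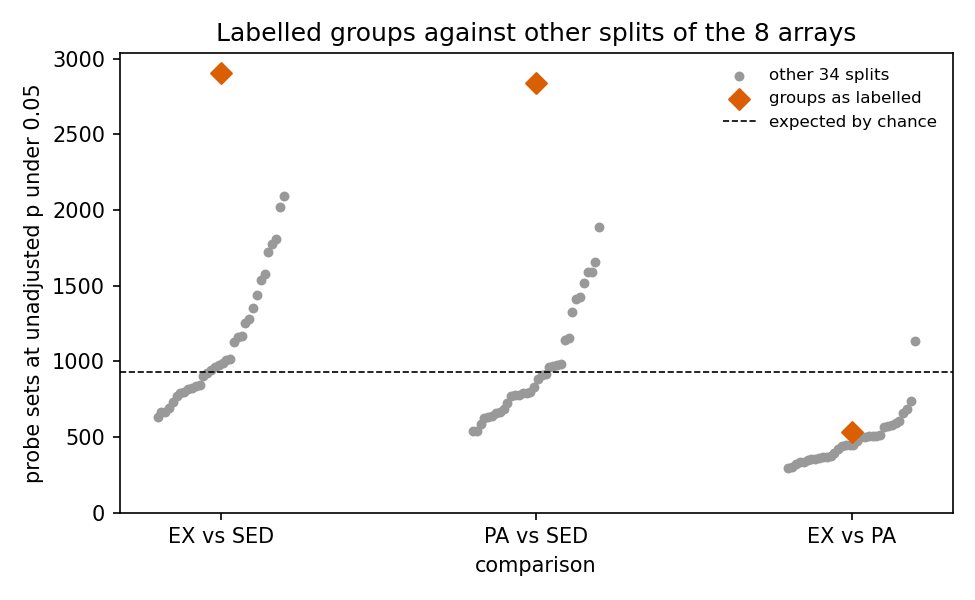
Number of probe sets at an unadjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), for the groups as labelled (diamonds) and the other splits of the same 8 arrays (grey points), with a dashed line at the 931 expected by chance. The labelled groups give 2906 in EX against SED and 2840 in PA against SED, above all other splits. In EX against PA they give 534, within the 293 to 1136 of the other splits, of which the next highest is 739.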

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

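All tests of SED 1 and of SED 3 here, except the rank correlation of SED 1 and the splits for the leukocyte list, were chosen after the result was seen. The runs that leave out 1 array were planned, and only the use of the run without SED 3 as a test of that array was chosen after. In each group of 4 arrays, the gap of the highest or lowest array to its neighbour was set against the range of the group for 129 sets of values, of which 4 stood out where chance gives about 6.45. They are the mean correlation of SED 1 with the other arrays (0.964, other SED arrays 0.987 to 0.988), its Gapdh 3' minus 5' difference (1.56, others 1.14 to 1.2), Ppargc1a in SED 1 (10.20, others 10.68 to 10.76) and Grpca in PA 4 (6.95, others 7.07 to 7.08).

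SED 1 differs from the other 11 arrays in correlation, spread of signal and 3' to 5' ratio. A monotone compression of the signal scale is argued against by rank correlation, which stayed at 0.954 for SED 1 against 0.981 to 0.985 for the others. A smaller amount of labelled sample, read from the spiked bioB control, is argued against as the whole cause, since SED 4 had a higher bioB signal (11.19 against 11.03) and a mean correlation of 0.987, though the next narrowest interquartile range (3.73). Degraded RNA may contribute and stays open: the Gapdh difference of 1.56 lay over the highest other array (1.35) by more than the SD of the others (0.0933), but for beta-actin the 1.70 of SED 1 was within 1 SD (0.102) of the highest other value of 1.67. A real difference of the pooled animals was not tested.

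The lower leukocyte list in EX and PA is a pattern that rests on SED 3, since the adjusted camera p without that array was 0.389 and 0.831. Chance is not excluded: 31 of the 35 splits of the EX and SED arrays and 30 of the 35 of the PA and SED arrays put as many lists past the threshold, with 1 list in the labelled groups and at most 4 and 6 in another split. Added blood in SED 3 stays open: the blood-cell list was highest there (0.82, next 0.27 in SED 4), while the hemoglobin genes Hbb and Hba-a3 had a mean of 10.72 there, within the 10.27 to 11.01 of the other arrays (0.16 and 0.05 above their own means), and the high signal of Hbb would hide a small share. Another candidate explanation that stays open is more leukocytes in the tissue of 1 or more animals of that pool, from heart muscle or from tissue dissected with it, which was not tested. For EX against PA, where 0 lists passed, all 35 splits necessarily gave as many (at most 5 in another split), which decides nothing.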

How the results depend on the processing

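Cyclic loess, EX and PA together, the setting without SED 1 and SED 3 together, and an estimated correlation with SED 1, EX 4 or both SED 1 and SED 3 left out were chosen after seeing the data. Of 183 alternatives of the counts, list counts and the correlation, 136 stayed close (counts within 1.5 times, the correlation within 0.05), 24 lost a call, 11 gained one and 12 moved. Where no cause is given, the cause was not tested. In EX against SED the 0 called probe sets became 4 at a threshold of 0.1, 8 with array weights and 2 with averaged probe sets, where fewer rows are tested. With array weights PA against SED had 1, EX against PA 1 and the F test 6. Leaving out an array gave 0 to 2 in EX against SED, 0 in PA against SED, 0 in EX against PA and 0 to 2 in the F test. The 1 list in each SED comparison became 0 with an estimated correlation and 0 with fry, 0 in PA against SED without a filter, and 0 to 2 when an array was left out. With an estimated correlation it was 0 in both without SED 1, 0 in both without SED 1 and SED 3, and 0 in EX against SED without EX 4. Without SED 1 and SED 3 by camera's preset it was 0 in PA against SED and 1 in EX against SED, where the list changed: leukocytes did not pass (adjusted p 0.0769) and oxidative phosphorylation was lower (0.0228, or 0.97 with an estimated correlation). In EX against PA the 0 lists became 0 to 2. The correlation of the responses was 0.697 to 0.841 with an array left out and 0.228 with the SED arrays split. Over its alternatives the adjusted camera p of the leukocyte list ran from 7.79e-08 to 0.995 in EX against SED and from 2.16e-05 to 0.998 in PA against SED. For EX and PA together the 135 calls became 1 after cyclic loess (1 higher), 1 after quantile normalization, 289 with array weights (126 higher, 163 lower), and 0 to 445 with an array left out.

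Replicate numbers did not pair the arrays: the 12 same-number pairs had correlations of -0.208 to 0.134, 4 were over 0.1, and 2 of 12 arrays matched their own number best. With the replicate number as a block, 0 probe sets were called in each comparison and in the F test, and the lists past the threshold stayed at 1, 1 and 0.

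Of 1124 alternatives of 60 named-gene values, 1080 kept their sign and side, 5 passed the threshold and 39 changed sign, none for a gene named for its small p and none for a value over 0.21 in size. With an array left out, the ranges in EX against SED were -0.0242 to 0.25 for Nppb, -0.0108 to 0.0125 for Atp2a2, -0.0117 to 0.18 for Ppargc1a and -0.15 to 0.13 for Dbp. In PA against SED they were -0.0267 to 0.25 for Nppb, -0.19 to 0.00083 for Myh7, -0.0067 to 0.0233 for Atp2a2, -0.0142 to 0.31 for Pdk4 and -0.0058 to 0.27 for Dbp. Of values that kept their sign there, Nppa ran from 0.03 to 0.50, Hspa1a from 0.005 to 0.19, Ucp3 from -0.65 to -0.28 and Ppargc1a from 0.09, without SED 1, to 0.28. In EX against SED, Nppa ran from 0.12 to 0.59, Pdk4 from 0.0083 to 0.37, Myh7 from -0.36 to -0.15, Ucp3 from -0.45 to -0.09 and Hspa1a from 0.14 to 0.41. In EX against PA the ranges were -0.10 to 0.24 for Nppa, -0.0908 to 0.10 for Nppb, -0.0208 to 0.0092 for Atp2a2, -0.12 to 0.20 for Pdk4 and -0.0142 to 0.36 for Ucp3, and without a change of sign 0.06 to 0.29 for Hspa1a, -0.23 to -0.07 for Dbp, -0.23 to -0.07 for Myh7 and -0.13 to -0.06 for Ppargc1a. Array weights gave Nppb -0.0312 and Atp2a2 -0.00519 in EX against SED, and Nppa -0.0268, Nppb -0.0462 and Dbp -0.0426 in PA against SED. Averaged probe sets gave Myh6 0.12 in both SED comparisons and Atp2a2 0.0312 in EX against PA. Centred medians gave Atp2a2 -0.0175 in EX against SED and Nppb -0.0075 in EX against PA. In EX against PA, Atp2a2 was 0.0102 after quantile normalization and 0.0113 after cyclic loess, which also gave Myh6 0.0059 in EX against SED and Dbp -0.0031 in PA against SED. The number of arrays limits these small values, and signal over background was not tested beyond the filter on dim probe sets.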

Other observations

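The comparison of EX and PA together with SED, its alternatives and its tests were chosen after the planned comparisons had called 0 probe sets, and the tests of small p-values, cyclic loess among them, after the data were seen. In a 2-group limma model of these 8 arrays against 4, 59 probe sets rose and 76 fell (135 past the threshold, 100 with 1 symbol, 99 genes). The genes below were chosen from that list after their values were seen. Vldlr, a receptor for triglyceride-rich lipoproteins, rose by 1.17 ± 0.17 (SE), from 5.79 ± 0.45 (SD, n = 4) in SED to 6.96 ± 0.20 (SD, n = 8) in the active groups, with an adjusted limma p of 0.049. Zbtb4 rose by 0.54 ± 0.08 and Dlg1, a scaffold protein at cell contacts, by 0.91 ± 0.16 (SE). The SED mean of Dlg1 was 4.78, under the filter on dim probe sets at 4.94. A dimmer probe set of Ppargc1a rose by 0.75 ± 0.13 (SE) at an adjusted limma p of 0.049, while its brightest was not called. Setd1a, a histone methyltransferase, fell by 0.61 ± 0.10 (SE), the desmosome gene Dsp by 0.37 ± 0.07, and Sct, which encodes secretin, by 1.04 ± 0.20. Sct had a mean of 5.12 in the active groups, near that filter. All 8 active arrays lay beyond all 4 SED arrays for these 7 probe sets. As they were picked from probe sets called for small p-values, this was largely given by the selection and is no added support.

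These calls lie near the threshold: 134 of the 135 had an adjusted p of 0.048 or more. Without SED 1, 0 passed, with a smallest adjusted limma p of 0.0787. All 135 kept their sign and an unadjusted limma p under 0.05 among 2779 such probe sets, with a median change 91.1% of that with all arrays. Since the 135 were picked for small p-values on mostly the same arrays, this was largely given by the selection and is no independent support. The count was 445 without SED 3, 2 without EX 2, 3 without SED 2, and 0 without any 1 of the other 8 arrays. Over all probe sets in 5 groups of rising signal, the median change was -0.08, 0.06, 0.13, 0.11 and 0.04, and after cyclic loess it was between -0.0069 and 0.03.

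If the arrays are independent units, chance is argued against as the source of the 2906 probe sets in EX against SED and the 2840 in PA against SED. In each, 1 of 35 splits, the labelled one, gave as many, and the highest others gave 2090 and 1890. Without SED 1 the counts were 2613 and 2282 against 2126 and 1758, again 1 of 35 each. After cyclic loess they were 2507 and 2305 against 1956 and 1701, also 1 of 35 each. On the same assumption these counts argue against SED 1 alone and against signal-dependent scale differences as the whole cause. The share of 1 of 35 is the smallest that these splits can give, and both comparisons use the same SED arrays. Whether arrays of a group share animals is not settled, and shared animals could set the labelled split apart without a difference between the groups. For EX and PA together, 100 of the 495 splits were compared, with the labelled one put in and the others drawn. Only the labelled one gave as many as 135 calls, and the highest other gave 1. At an unadjusted p under 0.05 the labelled groups gave 3731 probe sets and the highest other split 3007. This grouping was chosen after the SED comparisons on these same arrays were seen, and the share of 1 of 100 does not allow for that choice. With the Gapdh 3' minus 5' difference and the bioB signal as covariates the median change of these 135 was 89.6% of its size (0.51 with a median SE of 0.0989 before, 0.45 with 0.0932 after), and after cyclic loess it was 94.9% (0.48 with 0.0988), yet 0 and 1 stayed past the threshold. The 135 were picked for their change on these same arrays, so the size they kept is no independent support. Their median unadjusted limma p went from 0.000197 to 0.000663 with covariates (8 residual degrees of freedom against 10) and 0.00037 after cyclic loess, and probe sets at an unadjusted p under 0.05 went from 3731 to 2598 and 3143, both of which raise adjusted p-values, with the share of each not tested. Whether activity, animals shared between arrays of a group, or a technical difference that follows the SED group, such as a shared day of preparation, lies behind it stays open, since no test here separates them.

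At the adjusted threshold, where 0 probe sets were called, the splits decide nothing, since every split gives as many: all 35 in EX against SED (at most 0 in another split), in PA against SED (at most 1) and in EX against PA (at most 0), and all 100 compared for the F test, the labelled one among them (at most 1 in another split).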
